A study of Mus musculus with 9 samples.

How the data were processed

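Bulk RNA-seq had been run on 2 sorted populations of mouse bone marrow, LSK cells and Ly6G-positive neutrophils, from animals aged 4 to 12 weeks. Per the labels, RNA was isolated with RNeasy Micro columns and turned into libraries with the SMART-Seq v4 Ultra Low Input kit, which amplifies polyadenylated RNA from few cells and does not keep the strand. The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2 without versions or settings, and the builds mm10 and GRCm38; the gene annotation and the use of strand in counting are not given in the sources used here.

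The authors deposited, for each population, a table of raw read counts per gene, which were the values used in all tests. They also deposited a table of normalized values for each population (unit: signal). These equalled the raw counts divided by a single factor per library, which was 1.01 and 1.09 in the wild-type LSK libraries, 0.979 and 0.938 in the knockout LSK libraries, 1.10 and 1.31 in the wild-type neutrophil libraries, and 1.10, 1.01 and 0.681 in the knockout neutrophil libraries. The normalized tables served only to check the Spop level. Because the populations had been normalized apart, levels were not compared between them.

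The LSK table held 37187 genes by Ensembl identifier, of which 35412 had a symbol in the GENCODE M21 annotation of GRCm38; the others took at most 0.401% of the reads of a library. The neutrophil table held 45076 gene symbols, of which 41706 were in that annotation. For fits over both populations 35217 genes were joined by symbol, 786 of them through an older name. Neither table listed genes encoded in the mitochondrial genome, so that sign of RNA quality was not read. Coordinates and exon overlaps were taken from the same annotation. Without strand, reads of a gene and of an antisense partner cannot be told apart: 11.3% of the exon bases of Myd88 are shared with the opposite-strand gene Acaa1a, 15.0% of those of Mpo with an antisense transcript and 19.4% of those of Txnip with another. Values of the globin, stefin (Stfa) and MHC (H2) families are uncertain, because reads can be split between similar copies.

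Libraries were grouped by genotype and population as their titles state: 2 wild-type and 2 knockout LSK libraries, and 2 wild-type and 3 knockout neutrophil libraries. The second LSK knockout library carries the neutrophil entry in its cell type field, while its title and source name say LSK; it held 0 reads of Ly6g, as did the other LSK libraries, and stayed in the LSK knockout group. No label says that replicates of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. The counts of replicates differed by more than sampling noise (chi-square per gene of at least 9.84), so each counted once.

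Within each population, counts were tested with edgeR 4.0.16 (R 4.3.3), using TMM factors, the package's expression filter by group, a robust quasi-likelihood fit and its F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are counts-per-million values (CPM) scaled by TMM, and errors are standard deviations over libraries or standard errors (SE) of the log2 fold change. The difference between the effects of genotype in the 2 populations was tested as an interaction in a single fit of all 9 libraries. Fixed lists of genes (42 lists, for cell states, pathways, other cell types and RNA quality) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, wherever at least 5 members passed the filter. This gave 40 lists in LSK cells and 39 in neutrophils, with adjustment over the lists of a population. The same lists were tested with an estimated correlation and with fry, which asks whether a list moves on balance in 1 direction and uses the spread between libraries.

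The designs, lists, alternatives and the rule for the genes named were written before the data were examined. The rule took Spop, then the genes of largest change in each direction among those past the threshold with a mean log2 CPM of at least 2, complete separation of the genotypes and a name that is not a clone or predicted gene (at most 12 in each direction), then up to 4 members with the smallest p of each list described, and Myd88, Il1r1, Tlr2 and Tlr4. Where fewer than 5 genes passed, the 10 genes with the smallest unadjusted p were taken. The text names part of that set. Results of some genes are not reported here.

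The LSK libraries held 18827892 to 20264417 counted reads and the neutrophil libraries 21012702 to 27434086. Reads without molecular identifiers are not independent molecules, so a floor of 3 reads (0.109 to 0.159 CPM) covers counting error only. Where a group lay at or near that floor, levels are given and no fold, except for fitted values of Il1r1 and the Y-linked genes in neutrophils. Such fitted values, and medians of lists with members near the floor, are no bounds. The procedure was tested on simulated counts with known changes in 50 genes per fold size. The changed genes were drawn only from those with a mean above 4 CPM, so recovery of lower genes was not measured. Each gene was given the spread of the fitted trend at its level, without a spread of its own or an outlying library. In the LSK design it recovered 48.0%, 80.0%, 100.0% and 100.0% of genes changed 1.5-, 2-, 4- and 8-fold among 12779 genes, with 7 false calls. In the neutrophil design it recovered 0, 0, 20.0% and 42.0% among 12508 genes, and for the interaction 0, 0, 12.0% and 40.0% among 13499 genes, with 0 false calls in both. In a further simulation, genes were drawn independently and a list of 28 genes was raised 2-fold in knockout. Camera called that list in both populations. With an estimated correlation its adjusted p was 0.210 in LSK cells and 0.239 in neutrophils, so that form did not call it. With fry its adjusted p was 0.0319 in LSK cells and 0.182 in neutrophils, so in neutrophils fry did not call it either. Independent genes favour the preset correlation of camera. Some real neutrophil lists had high estimated correlations, such as 0.706 (interferon-stimulated) and 0.903 (T and NK cells). The simulation does not show how the tests perform on correlated genes or on larger changes.

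Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 and upper-quartile scaling in edgeR, other filters on low counts, other thresholds, a shared fit of all libraries, the replicate number as a block, and leaving out each library in turn. Fits with a quality weight per library, without the genes of the Y chromosome and Xist, and without a pair of neutrophil libraries were added after the data had been seen. Tables were handled with pandas 2.3.3 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.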

Results

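Transcript levels were measured by RNA-seq in bone marrow of Spop knockout and wild-type mice. Spop is the substrate-recognition subunit of a cullin-3 ubiquitin ligase. The series addresses whether Spop holds back the blood-forming response to inflammation through MyD88, the adaptor protein that carries signals from Toll-like and interleukin-1 receptors. Of the 9 libraries, 4 came from LSK cells (2 wild-type, 2 knockout), the marrow fraction that holds haematopoietic stem cells and multipotent progenitors, and 5 from Ly6G-positive neutrophils (2 wild-type, 3 knockout). Counted reads per library ran from 18827892 to 20264417 in LSK cells and from 21012702 to 27434086 in neutrophils.

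The targeted gene was read first. Spop (chromosome 11, 95414080 to 95493406, plus strand, GRCm38) was at 380 and 390 CPM in the wild-type LSK libraries and at 312 and 306 CPM in the knockout LSK libraries, a log2 fold change of -0.32 (SE 0.0889, 95% confidence interval -0.51 to -0.13, adjusted p = 0.0118, edgeR quasi-likelihood test). That call was lost without the first or the second wild-type library (adjusted p = 0.0832 and 0.117). In neutrophils Spop stood at 135 and 194 CPM in wild type and at 158, 178 and 210 CPM in knockout (log2 fold change 0.15, SE 0.403, interval -0.81 to 1.10, adjusted p = 0.901). The deleted part of the gene is not given in the labels. Reads from the remaining exons still count, so the level of the whole transcript does not check the genotype labels in neutrophils.

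In knockout LSK cells, genes of granulocyte and monocyte precursors rose strongly. Mpo, the myeloperoxidase of azurophil granules (chromosome 11, 87793581 to 87804413), went from 1135 ± 265 CPM to 10647 ± 1791 CPM (SD, n = 2 each), a 9.38-fold rise (log2 3.23, SE 0.189, adjusted p = 4.41e-06, edgeR). The neutrophil serine proteases Ctsg and Prtn3 rose 7.24-fold (169 to 1222 CPM) and 5.25-fold (294 to 1544 CPM), and Ms4a3, a marker of granulocyte-monocyte progenitors, rose 18.6-fold (57.6 to 1072 CPM). The Fc receptor Fcgr3 rose 4.83-fold and Csf2rb, the shared beta chain of the GM-CSF, IL-3 and IL-5 receptors, 3.52-fold. Of the 24 genes of the granulocyte-monocyte priming list, 20 rose and 1 fell (21 and 1 when adjusted over the list alone). Their median log2 fold change was 1.64, with an adjusted camera p of 2.64e-09 (adjusted p = 0.289 with an estimated correlation). The 12 genes of primary granules share several members with the priming list, Mpo, Ctsg, Prtn3 and Ms4a3 among them, so the lists are not independent. They held 10 that rose and 0 that fell, also when adjusted over the list alone. Their median was 1.55 (camera adjusted p = 4.15e-06, adjusted p = 0.265 with an estimated correlation).

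**Figure D1:**
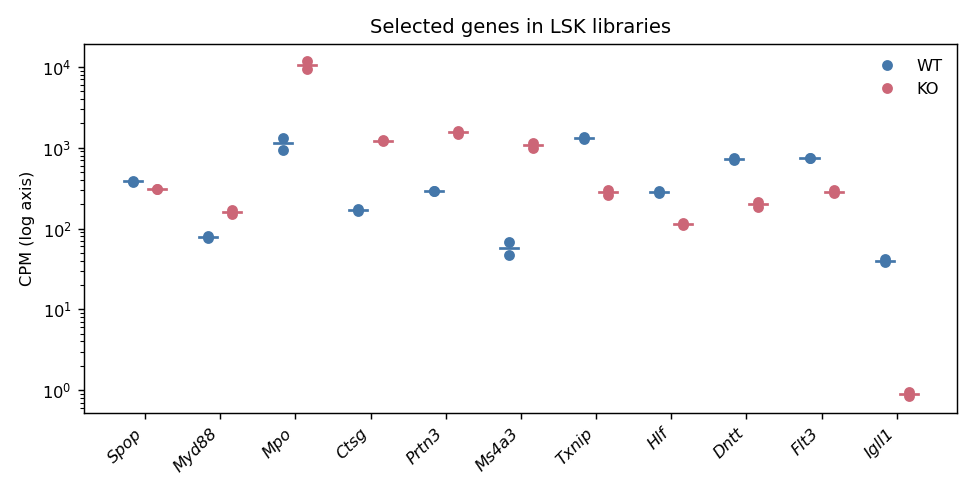
CPM (log axis) of 11 genes in the 4 LSK libraries, wild type in blue and knockout in red, each point a library and each bar a mean. Mpo, Ctsg, Prtn3 and Ms4a3 lie higher in both knockout libraries, and Txnip, Hlf, Dntt, Flt3 and Igll1 lie lower in both.

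Genes of secondary granules moved apart. Lcn2, an iron-chelating granule protein, rose from 1.83 to 57.2 CPM (31.2-fold), the NADPH oxidase subunit Cybb from 7.09 to 90.1 CPM (12.7-fold) and the chitinase-like gene Chil3 from 2.18 to 15.7 CPM. Hp, haptoglobin, rose from 12.7 ± 6.13 to 356 ± 18.5 CPM (adjusted p = 0.00197). Its call was lost without either knockout library (adjusted p = 0.122 without the first and 0.114 without the second). Mean levels were lower in knockout for Ngp (7.36 to 0.810 CPM), Ltf (1.72 to 0.237 CPM) and Camp (2.13 to 1.25 CPM). Of the 13 genes tested, 6 rose and 3 fell (7 and 3 when adjusted over the list alone). The median was 1.19 (camera adjusted p = 0.0370, adjusted p = 0.381 with an estimated correlation), and the list did not pass without the first knockout library (adjusted p = 0.0705). Without the second the median was 0.77. In the list of other neutrophil markers, which shares several of these genes, 4 of 10 tested genes rose and 2 fell (4 and 3 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.261). Its members summed to 39.0 and 51.8 CPM in wild-type and to 181 and 119 CPM in knockout LSK libraries.

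Outside the lists, the genes with the largest rises included Lrg1, a secreted glycoprotein (0.0938 CPM in wild type and 16.2 CPM in knockout), Prom1 (0.537 to 20.1 CPM), the tight-junction gene Cldn15 (1.27 to 43.3 CPM) and Dmkn (1.32 to 44.2 CPM). Large rises were also seen for the myeloid receptor gene Trem3 (6.07 to 153 CPM, 25.1-fold), the sphingomyelin synthase Sgms2 (1.49 to 38.6 CPM), Mefv, which encodes pyrin (0.902 to 17.0 CPM), Tmem215 (17.3-fold) and Mtus1 (16.7-fold). Ccr2, the chemokine receptor of monocytes, rose from 23.5 to 236 CPM, while the macrophage complement genes C1qb (11.4 to 0.368 CPM) and C1qc (7.97 to 0.315 CPM) fell. In the list of monocytes and macrophages as a whole 8 genes rose and 11 of 20 fell, also over the list alone (camera adjusted p = 0.568).

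Proliferation genes rose together in knockout LSK cells. In the S phase list 26 of 28 genes rose and 0 fell, the same counts as when adjusted over the list alone. The list had a median log2 fold change of 0.80 (camera adjusted p = 3.19e-10, adjusted p = 0.289 with an estimated correlation). Among its genes were the ribonucleotide reductase subunit Rrm2 (3.17-fold) and the chromatin remodeller Hells (2.65-fold). In the G2 and M phase list 24 of 28 genes rose and 0 fell, likewise when adjusted over the list alone (median 0.93, camera adjusted p = 8.95e-10, adjusted p = 0.265 with an estimated correlation). The mitotic kinases Aurka and Bub1 rose 2.65-fold and 2.48-fold. Of 16 genes of quiescence and cell cycle inhibition, 11 fell and 1 rose, also over the list alone (median -0.92, camera adjusted p = 9.04e-05, adjusted p = 0.265 with an estimated correlation). Those that fell included the anti-proliferative genes Btg1 (log2 -0.92) and Btg2 (log2 -0.98) and the thioredoxin inhibitor Txnip (1308 to 280 CPM, log2 -2.22).

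Genes of protein folding and biosynthesis rose as well. So did heat shock genes, a list fixed for RNA quality (median log2 fold change 0.78, camera adjusted p = 3.59e-04, adjusted p = 0.380 with an estimated correlation). The unfolded protein response list held 19 genes that rose and 2 that fell of 25 (19 and 3 when adjusted over the list alone; median 0.84, camera adjusted p = 4.47e-07, adjusted p = 0.265 with an estimated correlation). Its smallest p-values belonged to the chaperone Hspa5 (1002 to 3038 CPM, 3.03-fold), the lectin chaperone Calr (2.77-fold), Sdf2l1 (126 to 480 CPM) and the asparagine synthetase Asns (4.90-fold). In ribosome biogenesis 24 of 25 genes rose (25 when adjusted over the list alone; median 0.65, camera adjusted p = 2e-08, adjusted p = 0.265 with an estimated correlation). Bop1 rose 1.91-fold and Rrp12 2.55-fold. Oxidative phosphorylation held 28 of 39 genes that rose (31 when adjusted over the list alone; median 0.41, camera adjusted p = 6.07e-07, adjusted p = 0.442 with an estimated correlation). The electron carrier gene Cyc1 rose 1.72-fold and Cox5a 1.55-fold. Of 21 genes of the cholesterol list, 17 rose and 1 fell, also over the list alone (median 0.81, camera adjusted p = 1.63e-07, adjusted p = 0.390 with an estimated correlation). The sterol demethylase Cyp51 rose 2.48-fold and the squalene epoxidase Sqle 2.13-fold. Interferon-stimulated genes rose by less: 18 of 40 rose and 1 fell (19 and 1 over the list alone; median 0.34, camera adjusted p = 0.00183, adjusted p = 0.662 with an estimated correlation). That median was 0.53 without the first knockout library and 0.18 without the second. With fry the interferon list and the oxidative phosphorylation list did not pass (adjusted p = 0.171 and 0.0512). Gbp3 rose 1.97-fold and Oas1a 1.79-fold.

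Stem cell and lymphoid genes fell. In the stem cell list 19 of 25 genes fell and 1 rose, also over the list alone (median log2 fold change -1.16, camera adjusted p = 5.96e-06, adjusted p = 0.265 with an estimated correlation). Hlf, a transcription factor of stem cells, went from 283 ± 14.5 to 114 ± 6.53 CPM (log2 -1.31, SE 0.0980, adjusted p = 1.17e-06, edgeR). Lower levels were also found for Mecom (log2 -1.30), Meis1 (log2 -0.96) and Pdzk1ip1 (log2 -1.93). Of 20 genes of lymphoid priming, 15 fell and 0 rose, also over the list alone (median -1.62, camera adjusted p = 6.07e-07, adjusted p = 0.265 with an estimated correlation). Flt3, a cytokine receptor of early lymphoid progenitors (chromosome 5, 147330741 to 147400489), went from 740 ± 5.23 to 284 ± 17.6 CPM (log2 -1.38, SE 0.0942, adjusted p = 5.89e-07). Dntt, the terminal transferase of early lymphocytes, went from 719 to 199 CPM, the adaptor Blnk from 24.6 to 3.82 CPM, and the recombinase gene Rag1 from 17.8 to 0.210 CPM. Most B cell genes lay low in both genotypes and lower in knockout, while the list summed to 391 and 466 CPM in wild type and to 285 and 318 CPM in knockout. Igll1, the surrogate light chain (chromosome 16, 16860671 to 16863985), went from 40.1 to 0.896 CPM, Cd79a from 24.0 to 1.32 CPM and Vpreb1 from 21.7 to 1.21 CPM. Near the floor in knockout were Ebf1 (21.1 and 0.319 CPM in wild type and knockout) and Vpreb3 (14.1 and 0.265). In that list 10 of 13 genes fell and 0 rose, also over the list alone (camera adjusted p = 2.78e-06, adjusted p = 0.380 with an estimated correlation).

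**Figure D2:**
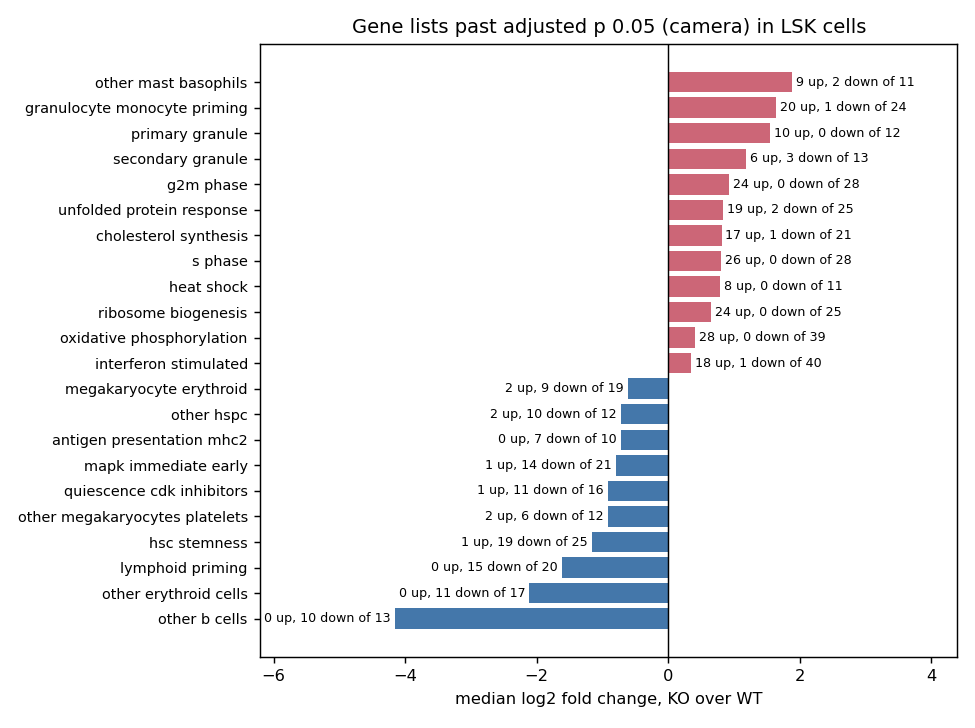
Median fitted log2 fold change, knockout over wild type, of the 22 gene lists past an adjusted camera p of 0.05 in LSK cells, with the number of genes that rose and fell and the number tested beside each bar. The 12 lists with higher genes include granulocyte-monocyte priming (1.64), and the 10 with lower genes include lymphoid priming (-1.62).

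Megakaryocyte and red cell genes were lower with exceptions. Of 19 tested genes of the megakaryocyte and erythroid list, 9 fell and 2 rose, also over the list alone (median -0.62, camera adjusted p = 0.0305, adjusted p = 0.522 with an estimated correlation). That list was not called without the second wild-type library (adjusted p = 0.0663) or the first knockout library (0.107). The platelet chemokine Pf4 fell 5.81-fold (85.1 to 14.6 CPM) and the carbonic anhydrase Car2 went from 963 to 396 CPM, whereas Tfrc, the transferrin receptor, rose 7.41-fold (38.3 to 284 CPM). The red cell and platelet lists of other cell types share genes with the megakaryocyte and erythroid list, Car2 and Pf4 among them. In these lists, 11 of 17 erythroid genes fell and 0 rose (12 and 0 over the list alone, camera adjusted p = 1.23e-05, adjusted p = 0.442 with an estimated correlation). The beta-globin Hbb-bs stood at 9.59 and 0.0527 CPM and the blood group gene Rhd at 8.75 and 0.292 CPM in wild type and knockout. In the megakaryocyte and platelet list 6 of 12 genes fell and 2 rose (7 and 2 over the list alone; median -0.92, camera adjusted p = 0.0289, adjusted p = 0.380 with an estimated correlation). In the list of haematopoietic progenitors 10 of 12 genes fell and 2 rose, also over the list alone (median -0.72, camera adjusted p = 0.00204, adjusted p = 0.442 with an estimated correlation). That list shares Hlf, Mecom, Meis1 and others with the stem cell list and Flt3 with lymphoid priming, so it is not separate from them.

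Immediate-early and MHC class II genes were also lower. Of 21 immediate-early genes of MAP kinase signalling, 14 fell and 1 rose, also over the list alone (median -0.79, camera adjusted p = 3.56e-04, adjusted p = 0.380 with an estimated correlation). Without the first knockout library the median was -0.42 (camera adjusted p = 0.0191). The phosphatase genes Dusp2 and Dusp6 had log2 fold changes of -1.57 and -1.60. Of 10 MHC class II genes, 7 fell and 0 rose, also over the list alone (median -0.72, camera adjusted p = 0.0145, adjusted p = 0.522 with an estimated correlation). H2-Ab1 fell from 150 to 85.5 CPM and the costimulatory gene Cd86 from 23.6 to 7.27 CPM.

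The Myd88 transcript (chromosome 9, 119335934 to 119341411, minus strand) rose 2.07-fold in knockout LSK cells, from 77.9 ± 2.58 to 161 ± 12.8 CPM (log2 1.05, SE 0.105, adjusted p = 9.44e-06, edgeR). MyD88 protein was not measured, so transcript levels do not test whether Spop acts on it. Tlr2 and Tlr4 had log2 fold changes of 0.49 (adjusted p = 0.0373) and 0.34 (0.0395). Both calls were lost with upper-quartile scaling (adjusted p = 0.0770 and 0.123), without the first wild-type library (0.233 and 0.0907), the second (0.0709 and 0.218) or the second knockout library (0.298 and 0.0582). Il1r1 did not pass (125 and 121 CPM, adjusted p = 0.785). The Toll-like and interleukin-1 receptor list as a whole did not pass: 7 of 33 genes rose and 5 fell (4 and 2 over the list alone; camera adjusted p = 0.918), with a median of -0.04 and a mean of 0.11. Cd14, a co-receptor for lipopolysaccharide (1.32 to 7.17 CPM), and the interleukin-33 receptor Il1rl1 (5.50 to 22.5 CPM) rose, and Tlr7 fell (52.2 to 19.2 CPM). The list of Spop complex members and reported substrates held 6 of 27 genes that rose and 7 that fell, also over the list alone (camera adjusted p = 0.894).

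Across 13008 genes tested in LSK cells, 5494 passed (2738 up and 2756 down), 587 of them more than 2-fold up and 1163 more than 2-fold down. With upper-quartile scaling 2207 rose and 3445 fell, a share of 39.1% up in place of 49.8%. That scaling moved the median log2 fold change of all genes from -0.03 to -0.13. The genotypes separated completely at 72.9% of genes, where chance gives 33.3%. The spread was estimated from 2 libraries per genotype. Without the first wild-type library 3524 genes passed, and in a fit sharing its spread with the neutrophil libraries 0 genes passed. None of the 22 list calls held with an estimated correlation, and 17 of them held with fry. Lost with fry were the interferon-stimulated (adjusted p = 0.171), oxidative phosphorylation (0.0512) and megakaryocyte and erythroid lists (0.1). The MHC class II list and the mast cell and basophil list were lost too (fry adjusted p = 0.0716 for each).

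In knockout neutrophils, genes of the interferon response and of mature neutrophils were higher as lists, and genes of B cells, of T and NK cells and of MHC class II were lower. None of these list calls held with an estimated correlation (adjusted p = 0.635 for each) or with fry (smallest adjusted p = 0.354). The interferon-stimulated genes summed to 3663, 9639 and 5302 CPM in the knockout libraries and to 1822 and 2141 CPM in wild type, and their median log2 fold change was 1.68 (0.90 without the second knockout library). No single gene passed the test, and the libraries of a genotype differed widely. The second wild-type library stood apart. Its B cell genes summed to 4521 CPM, against 95.5 CPM in the first wild-type library and 10.7, 4.27 and 124 CPM in knockout. Its T and NK cell genes summed to 1697 CPM (38.8 in the other wild-type library, 12.0, 43.9 and 16.8 in knockout) and its MHC class II genes to 26648 CPM (835, then 197, 420 and 207). Neutrophil markers summed to 40000.1 CPM in that library and to 234132, 242715, 270167 and 692071 CPM in the others. The third knockout library carried 18744 CPM of red cell genes (1813 and 3789 in wild type, 43.7 and 4.74 in the other knockout libraries). The calprotectin subunit S100a8 took 18.2% of the reads of that library. The ribosomal RNA entry Rn18s-rs5 took 3.68% of reads in the second wild-type and 2.86% in the third knockout library. It took 0.782% in the first wild-type library and 1.47% and 1.33% in the other knockout libraries.

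**Figure D3:**
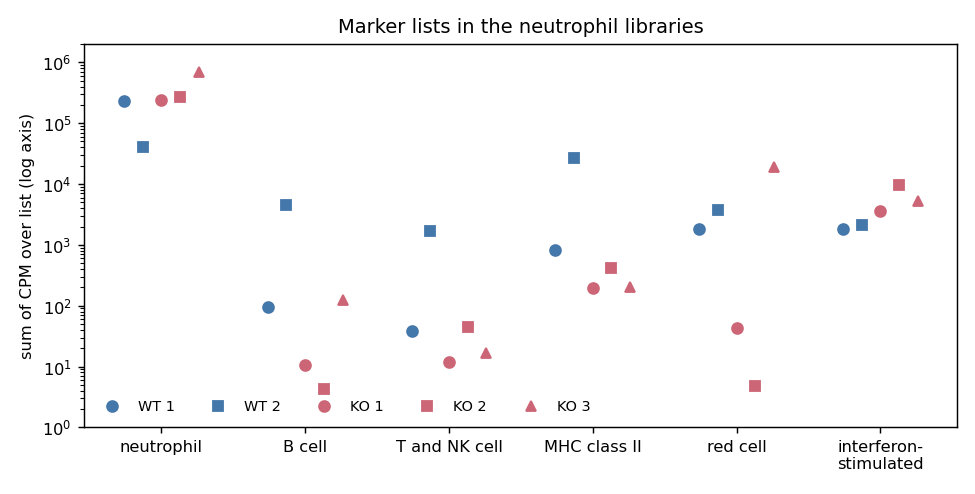
Summed CPM (log axis) of 6 gene lists in each of the 5 neutrophil libraries, wild type in blue and knockout in red. The second wild-type library holds 4521 CPM of B cell genes and 40000.1 CPM of neutrophil genes, and the third knockout library 18744 CPM of red cell genes.

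Reads of sex-linked genes also divided the neutrophil libraries by genotype. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 1 read in each wild-type library and 2180, 2284 and 2222 reads in the knockout libraries. Xist, the RNA of the inactive X chromosome, had 300 and 2993 reads in wild type and 0, 5 and 0 in knockout. These Y-linked genes were among those with the smallest p, though none passed (adjusted p = 0.0542 for Eif2s3y, 0.0556 for Ddx3y and 0.189 for Uty and Kdm5d, edgeR). The rest of the 10 genes with the smallest p were lower in knockout. These were the neonatal Fc receptor Fcgrt (46.7 and 0.502 CPM in wild type and knockout), the prostaglandin dehydrogenase Hpgd (60.1 and 0.177), the lectin Cd209a (53.6 and 0.0121) and Nav1 (13.6 and 0.0749). The last of them were Cmtm3 (27.7 ± 4.32 and 3.67 ± 0.665, log2 -2.91) and Padi2 (43.3 ± 2.91 and 0.324 ± 0.328), with adjusted p from 0.143 to 0.207.

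**Figure D4:**
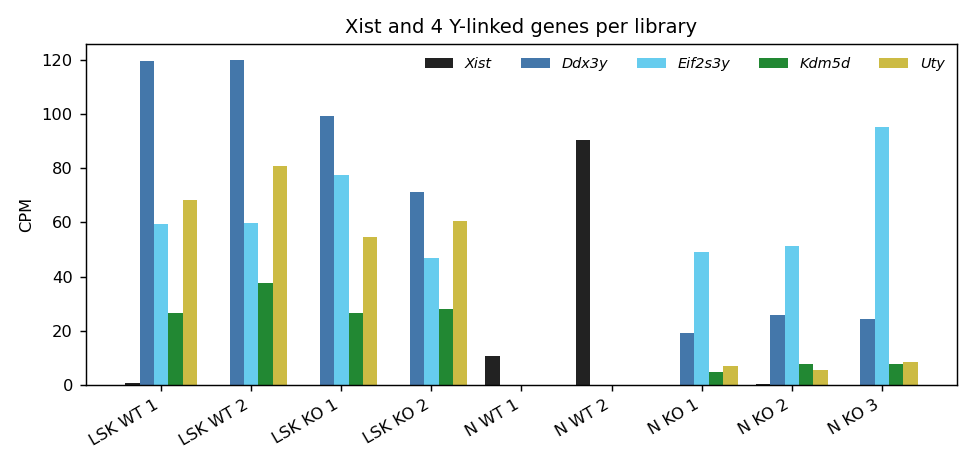
CPM of Xist and of 4 Y-linked genes in each of the 9 libraries, as bars from 0. The wild-type neutrophil libraries had 1 read each of the Y-linked genes, and the knockout neutrophil libraries at least 2180.

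Interferon-stimulated genes were higher in knockout neutrophils as a list. Of its 40 genes 38 had a positive fold change, 9 passed when adjusted over the list alone and 0 over all genes (median log2 fold change 1.68, camera adjusted p = 3.05e-09, adjusted p = 0.635 with an estimated correlation). Rtp4, a receptor transporter, stood at 41.6 and 42.9 CPM in wild type and at 157, 272 and 197 CPM in knockout. Means of the oligoadenylate synthetase genes were 46.4 and 315 CPM for Oas3, 58.0 and 369 CPM for Oasl2 and 10.2 and 87.1 CPM for Oasl1. Genes of tertiary granules and mature neutrophils were higher too, with 20 of 22 positive. Of these 6 passed when adjusted over the list alone and 0 over all genes (median 1.79, camera adjusted p = 1.03e-08, adjusted p = 0.635 with an estimated correlation). Among the members of smallest p were the cysteine protease inhibitors Stfa2l1 and Stfa1. Stfa2l1 stood at 15.5 and 11.4 CPM in wild type and at 144, 335 and 133 CPM in knockout. Stfa1 stood at 5.16 and 1.27, then 121, 512 and 134 CPM. The antiprotease gene Wfdc17 was another (113 and 290, then 1215, 1207 and 1443 CPM). Members of this list summed to 80617 and 24622 CPM in wild type and to 130364, 132334 and 482440 CPM in knockout. Without the second wild-type library the medians were 2.20 for the interferon list and 1.19 for the mature neutrophil list (camera adjusted p = 4.63e-09 and 1.21e-05). The interferon median was 0.90 without the second knockout library (camera adjusted p = 2.42e-06). The mature neutrophil median was 2.95 without the first wild-type library. With the second wild-type and the third knockout library both left out, the mature neutrophil median was 0.88. Without the second wild-type library fry, which uses the spread between libraries, gave 0.672 and 0.145.

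In the Toll-like and interleukin-1 receptor list 28 of 34 genes were positive in knockout neutrophils, 1 passed over the list alone and 0 over all genes (median 0.56, camera adjusted p = 4.31e-04, adjusted p = 0.635 with an estimated correlation). Il1rap, the accessory chain of the interleukin-1 receptor, stood at 10.7 CPM in both wild-type libraries and at 54.0, 44.1 and 48.0 CPM in knockout. The decoy receptor Il1r2 had means of 193 and 1739 CPM and Cd14 of 31.1 and 190 CPM. Myd88 stood at 156 and 118 CPM in wild type and at 274, 345 and 236 CPM in knockout (log2 1.06, SE 0.431, adjusted p = 0.345). Tlr2 (log2 1.59, adjusted p = 0.328) and Tlr4 (log2 1.70, adjusted p = 0.248) did not pass either, and Il1r1 was near the floor (at most 1.03 CPM). Genes of cholesterol synthesis were higher (19 of 20 positive, 0 past the threshold over the list alone, median 1.16, camera adjusted p = 1.22e-04, adjusted p = 0.635 with an estimated correlation), with the synthase gene Hmgcs1 at 6.75 and 36.5 CPM and Msmo1 at 40.9 and 124 CPM. The list summed to 327 and 260 CPM in wild type and to 862, 719 and 343 CPM in knockout. Of its genes, 7 were higher in every knockout than in every wild-type library. Genes of ribosome biogenesis were lower (24 of 25 negative, 3 past the threshold over the list alone, median -1.05, camera adjusted p = 7.53e-06, adjusted p = 0.635 with an estimated correlation), with Rrp9 at 13.1 and 2.82 CPM and Nop56 at 35.3 and 11.8 CPM. They summed to 561 and 878 CPM in wild type and to 525, 415 and 252 CPM in knockout, and 11 separated the genotypes completely. Without the second wild-type library these 3 lists had medians of 0.68, 1.16 and -0.69 (camera adjusted p = 4.35e-04, 0.00252 and 0.00204). The cholesterol median was 0.64 without the first knockout library (0.00685). With the second wild-type and the third knockout library both left out, the ribosome biogenesis list did not pass (median -0.48, 0.0638).

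Lists that moved with the second wild-type library were those of other cells and several of neutrophils. B cell genes were lower in knockout (11 of 12 past the threshold when adjusted over the list alone, camera adjusted p = 3.05e-09, adjusted p = 0.635 with an estimated correlation). Cd79b stood at 34.7 and 585 CPM in wild type and at most 5.69 CPM in knockout. T and NK cell genes (16 of 20 over the list alone, 3.47e-07), MHC class II genes (8 of 10, 3.32e-06), dendritic cell genes (8 of 12, 9.53e-06), monocyte and macrophage genes (13 of 20, 1.86e-07) and lymphoid priming genes (9 of 17, 8.21e-04) were lower, each with adjusted p = 0.635 with an estimated correlation. Without that library the medians of these 6 lists shrank: B cells from -7.67 to -3.40, T and NK cells from -5.44 to -1.12, MHC class II from -7.33 to -2.83, dendritic cells from -3.70 to -1.41, monocytes and macrophages from -2.32 to -1.42 and lymphoid priming from -3.41 to -1.51. Their camera adjusted p then ran from 2.45e-10 to 0.0333. With the third knockout library left out too, the T and NK cell list did not pass (0.0928). Cd74, the MHC class II invariant chain, stood at 355 and 13177 CPM in wild type and at 10.1, 33.0 and 42.5 CPM in knockout. H2-DMa stood at 78.7 and 365 CPM against at most 15.7 CPM, Cx3cr1 at 20.5 and 64.7 CPM against at most 1.26 CPM and C1qc at 18.1 and 90.7 CPM against at most 4.16 CPM. Secondary granule genes (median 0.88, camera adjusted p = 4.31e-04, adjusted p = 0.674 with an estimated correlation), glycolysis genes (0.77, 4.46e-04 and 0.635) and other neutrophil markers (1.54, 1.02e-04 and 0.635) were higher. Without that library they did not pass (medians 0.0465, 0.27 and 0.67, adjusted p = 0.700, 0.111 and 0.111), and without the first wild-type library their medians were 3.11, 1.72 and 3.51. The collagenase Mmp8 stood at 2729 and 452 CPM in wild type and at 5738, 8746 and 3265 CPM in knockout, and the glucose transporter Slc2a1 at means of 30.5 and 106 CPM. G2 and M phase genes (0.46, 6.59e-04 and 0.737) were higher and ribosomal protein genes (-0.89, 6.59e-04 and 0.737) lower, and both changed direction without it (-0.33 and 0.17). Without the first wild-type library their medians were 2.10 and -1.37. Heat shock genes (-0.65, 0.0205 and 0.635) did not pass without the second wild-type library (median -0.22, 0.139) or without the third knockout library (-0.35, 0.0772). Red cell genes had a positive median (0.43) beside a camera test pointing down (0.00612 and 0.737), a call that was lost without any 1 of the libraries other than the third knockout (adjusted p from 0.0511 to 0.361). Without the third knockout library their median was -5.64. In these last 7 lists 0 genes passed over the list alone.

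Of 12836 genes tested in neutrophils, edgeR called 0, with 1787 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0542; limma-voom called 0 and DESeq2 877. Without the first wild-type library, which leaves the library with most B cell reads as the only wild-type one, 601 genes passed (207 up and 394 down), and 0 without any of the others. With the second wild-type and the third knockout library both left out, 0 genes passed and 10 of the 18 list calls held. Of the 18 list calls 0 held with an estimated correlation or with fry. Neither called a raised list in simulated neutrophil counts. Genes there were drawn independently and the rise was smaller than the change of several of these lists, so the simulation does not explain the lost calls.

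The difference between the genotype effects in neutrophils and LSK cells was tested at 13815 genes, and 4 passed, all on the Y chromosome: Ddx3y, Eif2s3y, Uty and Kdm5d (adjusted p = 0.00536, 0.00536, 0.00543 and 0.0186, edgeR). Together they had 1 read in each wild-type neutrophil library. With the replicate number as a block, 0 genes passed. At an unadjusted p under 0.05 there were 2173 genes, DESeq2 called 1017 (4 of them Y-linked), limma-voom 11 (4) and limma-voom with quality weights 17 (0). The count was 1406 without the first wild-type neutrophil library (4 Y-linked), 13 without the second (4) and 7 without the third knockout neutrophil library (3), 2 without the second wild-type LSK library and 0 without either knockout LSK library.

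Fold changes in the 2 populations were weakly related across 11197 genes (Pearson r = 0.227, Spearman rho = 0.136; genes are not independent replicates), and r was 0.0545 without the second wild-type neutrophil library. Of the genes called up in LSK cells, 122 had an unadjusted p under 0.05 and the same direction in neutrophils, where independent lists would share 120.7. For lower genes the overlap was 392 against 208.5. Both overlaps were counted with the second wild-type neutrophil library included. Without it, genes that fell at least 2-fold in LSK cells had a median log2 fold change of -0.0205 in neutrophils, with 50.9% lower.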

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

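The tests of sex, of neutrophils in the LSK sort, of other cells in the second wild-type neutrophil library and of dilution in it were chosen after the results were seen; the test of gene length and GC content was written before its result was seen.

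The effect of genotype differed between neutrophils and LSK cells at 4 genes, by a test of the difference itself. Fitted differences in log2 fold change (neutrophils minus LSK cells) were 10.63 for Ddx3y, 11.58 for Eif2s3y, 11.35 for Uty and 11.17 for Kdm5d; being fitted against wild-type neutrophil libraries with 1 read of these genes together, they are no bounds. If the wild-type neutrophils came from females and all other libraries from males, the genes that pass should lie on the Y chromosome, and 4 of 4 did. Other fits also called genes off the Y chromosome (limma-voom 11 with 4 Y-linked, limma-voom with quality weights 17 with 0, edgeR without the second wild-type neutrophil library 13 with 4). The wild-type neutrophil libraries held 300 and 2993 reads of Xist and the knockout ones 0, 5 and 0, so sex is a likely cause of this difference at the 4 genes, in place of Spop.

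Granulocyte and monocyte genes were higher in knockout LSK cells. Mature neutrophils that slipped through the LSK sort, which selects against lineage markers, would bring Ngp, Camp, Ltf, S100a8 and S100a9, which stood at 20065 to 87131 CPM in the neutrophil libraries against 1618 CPM for Mpo. In LSK cells the summed change of these 5 genes was 0.125% of the 9512 CPM rise of Mpo, with Ngp going from 7.36 to 0.810 CPM, so such cells do not account for the rise. A trend of fold changes with gene length and GC content does not either, as the median of the priming list was 1.64 before and 1.83 after a loess fit of that trend was removed (SE of members 0.295; all 24 members had both values). Carry-over of monocytes or immature myeloid cells was not tested and stays open. The monocyte and macrophage list summed to 289 and 364 CPM in wild-type and to 1075 and 1461 CPM in knockout LSK libraries. Of its 20 genes 8 rose and 11 fell. Other hypotheses that stay open are changed expression within the same cells or a larger share of granulocyte-monocyte primed progenitors inside the LSK gate. Bulk libraries could not separate these.

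Several gene lists differed between the neutrophil genotypes, and for the lower B cell, T and NK cell and MHC class II lists, cells of other types in the second wild-type library are a likely source: its sums were at least 31.9 times the highest other library, although the sort on Ly6G should remove such cells, while its neutrophil markers were at 0.171 of the lowest other. Without that library their medians went from -7.67 to -3.40, from -5.44 to -1.12 and from -7.33 to -2.83 (camera adjusted p = 2.45e-10, 0.0333 and 1.86e-04), and the T and NK cell list did not pass without it and the third knockout library (0.0928). The sums of the first wild-type library lay within the knockout range for B cell genes (95.5 against up to 124 CPM) and T and NK cell genes (38.8 against up to 43.9 CPM). For MHC class II genes its sum lay above that range (835 against up to 420 CPM). The B cell sum of 124 CPM was that of the third knockout library, beside 10.7 and 4.27 CPM in the others. Gene by gene, both wild-type libraries lay above every knockout library for 11 of 12 tested B cell genes. This held for 13 of 20 T and NK cell genes and 8 of 10 MHC class II genes. The second wild-type library alone therefore does not account for the lower lists. The interferon-stimulated list summed to 2141 CPM in the second wild-type library, reads of its other cells included, and to 1822 CPM in the first. Leaving the second out moved the median from 1.68 to 2.20 (0.90 without the second knockout library). Dilution of neutrophil RNA in that library alone therefore does not account for the higher list, but 1 wild-type library was left. The SE of members (0.171) is over genes that move together (estimated correlation 0.706), not over libraries, so it does not measure the spread between animals. For the mature neutrophil list such dilution cannot be told apart from an effect of Spop. Its median fell from 1.79 to 1.19 (SE of members 0.390, median 2.95 without the first wild-type library) and 1 wild-type library was left. Sex could not be told apart from genotype either, since 0 neutrophil genotype groups held both sexes.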

How the results depend on the processing

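The quality-weighted fits, the fits without Y-linked genes and Xist, and those without the pair of neutrophil libraries rich in B cell or red cell reads (wild type 2 and knockout 3) were chosen after the data were seen; the other alternatives were planned. The cause of a change was not tested unless stated. Of 88 named genes called in LSK cells, all kept their call with DESeq2, limma-voom (with and without weights), DESeq2 scaling, either filter and the replicate block; 2 lost it with upper-quartile scaling, 7 with the 1.5-fold minimum, 1 to 3 without a library and 88 in the shared fit, where the spread pooled over both populations (biological coefficient of variation 0.491, against 0.126 in LSK cells alone) applies. No called LSK gene changed sign. In LSK cells 0 genes passed in the shared fit, 1578 with the 1.5-fold minimum and 3524 to 5718 without a library. Spop had a log2 fold change of -0.31 in the shared fit (adjusted p = 0.881), -0.32 against the 1.5-fold minimum and -0.33 to -0.30 without a library. Il1r1 went from -0.13 to 0.064 without a library. Of the 22 LSK lists, 0 passed with an estimated correlation, 17 of the calls held with fry, and 21 to 23 lists passed without a library.

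In neutrophils 334 genes passed without the filter, 2 with the strict filter, 877 with DESeq2, 562 in the shared fit, 2 at an adjusted p under 0.1 and 0 to 601 without a library. Il1r1 had log2 fold changes of 0.92 with limma-voom, 0.62 with weights, 3.25 without the pair of libraries and -0.94 to 3.65 without a library, at no more than 34 reads. Spop was at -0.0031 with upper-quartile scaling and -0.037 to 0.40 without a library. With an estimated correlation and with fry 0 lists passed, and 16 to 23 passed without a library. The G2 and M phase list had a median of -0.25 without the pair and -0.33 to 2.10 without a library, and ribosomal proteins -1.37 to 0.17. Of the 18 calls, 10 held without the pair, where ribosome biogenesis had an adjusted p of 0.0638. The interaction called 10 genes without the filter, 1017 with DESeq2, 11 with limma-voom, 17 with weights, 0 without Y-linked genes and Xist (a count fixed in advance, as all 4 calls were among them), and 0 to 1406 without a library. The correlation of fold changes was 0.136 by Spearman's rho, 0.0963 for genes of high CPM, 0.481 for genes at p under 0.05 in both and 0.0545 to 0.290 without a library.

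Replicate numbers are not stated to pair animals, and a check on the values could not settle it. Deviations of same-numbered libraries correlated at 0.0039 in LSK cells and at 0.239 and -0.024 in neutrophils. With 2 libraries in a group the deviations mirror each other, so such correlations can neither show nor exclude pairing. With the number as a block, 5776 LSK genes passed, 334 neutrophil genes and 0 in the interaction. The third number occurs only in knockout neutrophils, so the block gives that library a term of its own. It then adds nothing to the genotype effect in neutrophils, and the block cannot be told apart from leaving that library out. Il1r1 in neutrophils had a log2 fold change of 0.45. In that fit 23 LSK lists passed, with 22 calls held, and 21 neutrophil lists, with 17 held. Lists gained in neutrophils included the lower megakaryocyte and erythroid list (camera adjusted p = 1.4e-08 with the block and 0.0718 without). Fits without a library leave some groups with 1 library, assumed to vary like the rest. In neutrophils alone the coefficient was 0.608.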

Other observations

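The test of LSK changes in neutrophils was chosen after the results were seen.

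Genes of mast cells and basophils rose in knockout LSK cells. Of 11 tested, 9 rose and 2 fell, also when adjusted over the list alone (median log2 fold change 1.88, camera adjusted p = 0.00645, adjusted p = 0.522 with an estimated correlation). With fry the list did not pass (adjusted p = 0.0716). The histidine decarboxylase gene Hdc went from 16.7 to 108 CPM, the protease Mcpt8 from 12.8 to 41.5 CPM and the IgE receptor chain Ms4a2 from 2.63 to 11.5 CPM, while Kit, which stem cells share, fell from 1019 to 625 CPM. Heat shock genes, a list fixed for RNA quality, rose, 8 of 11 with 0 that fell, also over the list alone (median 0.78, camera adjusted p = 3.59e-04, adjusted p = 0.380 with an estimated correlation). Among them were the mitochondrial chaperone Hspd1 (2.24-fold) and Hsph1 (2.33-fold). Glycolysis as a list did not pass (15 of 25 rose and 6 fell, 15 and 7 over the list alone, camera adjusted p = 0.0540), with the phosphofructokinase Pfkp at 2.62-fold, Ldha at 2.13-fold and Eno1 at 2.19-fold, and the glucose transporter Slc2a3 at a log2 fold change of -1.21.

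In lists whose members went both ways in LSK cells, single genes moved far. Among genes of apoptosis (3 of 24 rose and 7 fell, also over the list alone, camera adjusted p = 0.680), the pro-apoptotic Pmaip1 rose from 3.35 to 34.8 CPM and the pro-apoptotic Bmf fell from 8.56 to 1.07 CPM. Among genes of cytokine and JAK-STAT signalling (9 of 24 rose and 3 fell, 10 and 4 over the list alone, camera adjusted p = 0.271), the feedback inhibitor Socs3 rose 2.29-fold and the receptor chain Csf2rb2 5.04-fold. Among NF-kB targets (4 of 29 rose and 11 fell, also over the list alone, camera adjusted p = 0.188), the chemokines Ccl3 (19.4 to 3.63 CPM) and Ccl4 (28.0 to 5.63 CPM) and the inhibitor Nfkbia (142 to 92.4 CPM) fell. Ribosomal protein genes, 3 up and 7 down of 44 (0 and 1 over the list alone), did not pass (camera adjusted p = 0.808). Of the other lists, none of the following passed in LSK cells: tertiary granules (3 up and 3 down of 15, camera adjusted p = 0.637), NADPH oxidase and reactive oxygen (6 and 2 of 15, 0.361), adhesion and migration (5 and 4 of 17, 0.737), MHC class I (5 and 3 of 16, 0.668), T and NK cells (2 and 5 of 14, 0.321), dendritic cells (2 and 4 of 10, 0.069), eosinophils (1 and 1 of 5, 0.738), stromal cells (0 and 3 of 6, 0.401) and replication histones (0 and 3 of 13, 0.680). The neutrophil lists that did not pass had camera adjusted p from 0.0718 to 0.684.

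A hypothesis was that Spop deletion moves the same genes the same way in both populations. Among the 11197 genes tested in both, the 513 that rose at least 2-fold in LSK cells had a median log2 fold change of 0.39 in neutrophils (camera p = 1.75e-04, p = 0.402 with an estimated correlation), and the 694 that fell -0.65 (p = 3.1e-06 and 0.205). Without the second wild-type neutrophil library the medians were 0.0653 (camera p = 0.879, p = 0.958 with an estimated correlation) and -0.02 (p = 0.0202 and 0.259). The quartiles of the members then lay at -0.55 and 0.71 for the first set and at -1.37 and 0.78 for the other (SD 1.72 and 2.36), against a single wild-type library, so whether the change is shared stays open.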
